A study of Mus musculus with 6 samples.

How the data were processed

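Cells positive for CD45, the surface protein carried by leukocytes, had been sorted from MC38 tumours and sequenced by droplet 5′ single-cell RNA sequencing together with an enrichment of T cell receptor (TCR) transcripts. MC38 is a mouse colon adenocarcinoma line, grown here under the skin. The 6 samples fall into 3 control samples (ctr, Ctcf intact in Treg cells) and 3 samples from mice with an inducible loss of Ctcf in Treg cells (cko), and the labels call them biological replicates.

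The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.0 on the mouse build GRCm38 (mm10), per the submitters' processing notes. They hold barcodes already called as cells, and samples were not pooled. The deposited contig tables list assembled TCR chains with their UMI and read counts, and every contig in them was productive. Any removal of doublets or free RNA before deposit is not given in the sources used here. Of 32285 gene identifiers, 32158 were found in the GRCm38 annotation that gave the coordinates.

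Cells were kept with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial counts. Scrublet scores were computed per sample. Its automatic threshold marked 175 barcodes, 0.420% of the total, which is too few to be a working call, so the cells with the highest scores were removed at a fixed share that grows with the number of barcodes. This took out 2084 cells. No cell had 3 or more TRB chains. Of 41679 barcodes, 37340 were kept, 18506 in the ctr and 18834 in the cko group.

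Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered on 15 nearest neighbours with the Leiden method at resolution 1. Genes for TCR and immunoglobulin segments, mitochondrial, ribosomal, cell cycle and sex-linked genes were left out of the variable genes. T and NK clusters were clustered again at resolution 1.5. This gave 34 clusters and, within T and NK cells, 29. A cluster took the class with the highest mean score over its markers among those with at least 3 detected markers and, in T and NK cells, with the matching Cd4, Cd8a, Trdc or Cd3e detection. Classes are therefore "like" their names (Treg-like and so on), and plain names are used for short. Some named clusters were led by other genes. In T and NK cells, clusters 10, 14 and 15 (CD8 T), 23 (NK) and 25 (γδ T) had no marker of their class among their 10 leading genes, and cluster 15 scored highest for naive or central memory T cells. Treg cluster 11 had 6 Treg markers among its 10 leading genes, but scored higher for the tumour or epithelial class, of which fewer than 3 markers were detected. Clusters whose median UMI count was under 0.333 of their own samples' medians stayed unnamed, even where markers led them, as NK markers led cluster 28 of the T and NK cells. The scoring rule and this treatment of low UMI counts were chosen after the data were seen. That ratio held 12.5% of ctr and 18.1% of cko cells out of the classes. The CD8 T cluster numbered 2 among T and NK cells had the monocyte marker Ly6c2 among its 10 leading genes when set against T and NK cells alone, but not when set against all kept cells.

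Raw counts were summed per sample and class. A class was tested for genes where every sample held at least 20 of its cells, which left out γδ T cells (6 in the smallest sample) and neutrophils (4). Sums were compared with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, robust fit), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. Log2 fold changes are cko over ctr with their standard errors (SE), and CPM values are means ± SD. The difference between the genotype effect in Treg and in conventional CD4 T cells was tested as an interaction with the sample as a block. Class shares used the same test on cell numbers, with all kept cells as the library size. Fixed gene lists with at least 5 tested members were compared with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. At the preset correlation, some other split of the samples called as many lists or more in every class but monocytes and macrophages.

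A clonotype is a paired TRA and TRB chain with the same V and J genes and CDR3 nucleotides, from the contig with most UMIs of each chain. Clonotype measures were averaged over 200 draws of equal cell numbers per sample. Clonotypes with at least 3 cells counted as expanded. Per-sample values were compared with exact two-sided permutation tests. With 3 samples against 3 there are 20 assignments, and the smallest p is 0.1. Intervals of single shares are Wilson intervals at 95% and cover counting error only. Foxp3-positive shares were computed after thinning each cell to 2597 UMIs.

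Tests, designs, class markers, gene lists and the rule for named genes were fixed before the data were examined. The rule takes key genes of each class whatever their result, up to 8 higher and 8 lower genes with the largest fold change among those past the threshold, with a mean of at least 20 CPM and no overlap between the groups, and up to 4 members of each called list with the smallest p. TCR and immunoglobulin segments and unnamed gene models were left out of it. Genes outside the rule are said to be chosen after their values were seen. The sum of cko replicates 1 and 3 into 1 sample was added after seeing that they share most clonotypes.

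Alternatives changed the size factors, the filter, the tool (DESeq2), the replicate block, the doublets, the resolution (0.6 and 1, or 1.5 and 2), the mitochondrial maximum (5%), the clonotype definition and each sample left out in turn. The fits were tested on simulated counts with 100 genes changed at each of 2 fold sizes. At a log2 change of 1 the test recovered 63% in Treg, 67% in conventional CD4 T, 72% in all CD4 T, 81% in CD8 T, NK and cDC, 85% in monocyte/macrophage sums and 49% for the interaction. At a log2 change of 2 these shares were 94% in Treg, conventional CD4 T and monocyte/macrophage sums, 96% in all CD4 T and NK, 97% in CD8 T, 95% in cDC and 87% for the interaction. False calls were 2.96% to 8.72% of all calls.

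Versions were Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Adjusted p-values in the text come from edgeR for genes and class shares and from camera for gene lists, unless another test is named.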

Results

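Leukocytes were profiled from subcutaneous MC38 tumours, a colon adenocarcinoma line, taken 25 days after inoculation of mice with intact Ctcf in Treg cells (ctr, n = 3) and of mice in which Ctcf was deleted in Treg cells by an inducible knockout (cko, n = 3). CTCF is a DNA-binding protein that holds chromatin loops and domain borders in place. Treg cells are the CD4 T cells that restrain other immune cells and depend on the transcription factor Foxp3. The matrices held 6850, 6125 and 7577 barcodes for ctr replicates 1 to 3 and 7151, 6530 and 7446 for cko replicates 1 to 3. Their total counts were 54224947, 54997772 and 55515267 UMIs in ctr and 46829114, 45322797 and 53473461 UMIs in cko. Kept cells had median counts of 6644, 7914 and 6162 UMIs in ctr and 5720, 5172 and 6293.5 UMIs in cko. Both TCR chains were found in 2395, 1504 and 2435 cells of ctr and 2641, 2239 and 2645 cells of cko.

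The T cells of cko replicates 1 and 3 carried the same clones. The pair shared 191 paired clonotypes out of 577 and 664. These held 2179 of 2641 receptor-bearing cells (82.5%, 95% interval 81.0% to 83.9%) in replicate 1 and 1846 of 2645 (69.8%, 68.0% to 71.5%) in replicate 3. Every other pair of samples shared 3 or fewer, and the 9 ctr–cko pairs shared none. Over genes, the chi-square per degree of freedom was 17.1 between these libraries and 51.0 to 196 between the other pairs within a group, which does not tell a pair of draws from 1 animal from a pair of animals. They were counted as separate samples, as labelled. Each leading count is therefore also given with them added together, an alternative chosen after seeing the data, and p-values measure the spread between these samples.

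**Figure D1:**
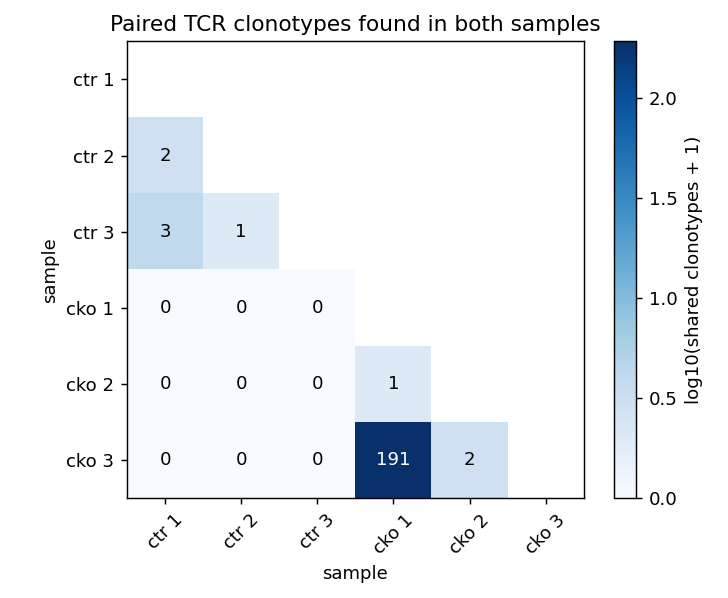
Number of paired TCR clonotypes shared by each pair of the 6 samples (rows and columns are samples, colour is log10 of the count plus 1). The pair of cko replicates 1 and 3 shares 191 clonotypes and every other pair 3 or fewer.

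Ctcf (ENSMUSG00000005698, GRCm38 chromosome 8, 105636568 to 105682922, plus strand) was measured first, as the deleted gene. In Treg sums it stood at 73.9, 84.1 and 90.5 CPM in ctr replicates 1 to 3 and at 49.1, 60.8 and 56.8 CPM in cko replicates 1 to 3. The mean fell by 0.58 on the log2 scale (SE 0.13, adjusted p = 0.0156; n = 3 per group), and with cko replicates 1 and 3 added together the adjusted p was 0.054. In the other classes it did not pass the test, with log2 fold changes of 0.15 in conventional CD4 T cells (adjusted p = 0.76), 0.25 in CD8 T (0.0786), -0.02 in NK (0.958), 0.03 in monocytes and macrophages (0.858) and -0.29 in cDC (0.228). The labels do not name the deleted exons, and counts from 5′ reads can come from parts of the transcript outside them.

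The first comparison asks how the makeup of the infiltrate differs when Ctcf is deleted in Treg cells. Treg cells fell from 11.5% ± 0.586 to 3.94% ± 0.111 of kept cells (SD, n = 3 per group), a log2 change of -1.55 (SE 0.18, adjusted p = 0.00295). NK cells, cytotoxic lymphocytes without a T cell receptor, fell from 6.72% ± 1.87 to 2.68% ± 0.632 (log2 -1.32, SE 0.33, adjusted p = 0.0318). γδ T cells, whose larger cluster was led by Il17a, Cd163l1 and Trdc, rose from 0.339% ± 0.202 to 2.43% ± 1.12 (log2 2.83, SE 0.67, adjusted p = 0.0318). Their smaller cluster, 25, had no γδ T marker among its 10 leading genes. It held 30.8% of ctr and 13.1% of cko γδ T cells. CD8 T cells stood at 20.5% ± 6.38 and 31.6% ± 7.07 and conventional CD4 T cells at 4.42% ± 2.15 and 7.71% ± 1.10. Monocytes and macrophages stood at 33.8% ± 10.3 and 21.2% ± 6.49. Each of these 3 classes had an adjusted p of 0.142. cDC, the conventional dendritic cells that prime T cells, stood at 6.77% ± 1.70 and 3.80% ± 0.411 (adjusted p = 0.0648). Neutrophils stood at 0.369% ± 0.363 and 1.36% ± 0.0792 (0.142; 0.0375 without ctr replicate 1). Treg cells made up 68.2% ± 7.68 of CD4 T cells in ctr and 26.4% ± 6.49 in cko, and there were 1.78 ± 0.548 and 8.04 ± 1.94 CD8 T cells per Treg cell (exact permutation p = 0.1 for both, the smallest that 3 against 3 allows). The CD4 to CD8 ratio was 0.873 ± 0.213 and 0.542 ± 0.308 (exact p = 0.2). Exact tests of the shares gave 0.1 for Treg, NK, γδ T, cDC and neutrophils and 0.2 for CD8 T, conventional CD4 T and monocytes and macrophages. All shares are of sorted CD45-positive cells, and clusters of low UMI count held 12.5% ± 1.26 of ctr and 18.1% ± 5.13 of cko cells. With cko replicates 1 and 3 added together the Treg call held. The adjusted p was then 0.0811 for NK and 0.0679 for γδ T cells. Naming the clusters of low UMI count by their markers, an alternative chosen after seeing the data, ended the NK call as well (log2 -0.83, adjusted p = 0.0650). The NK call was also lost without ctr replicate 1 (0.0906), ctr replicate 3 (0.0778), cko replicate 1 (0.116) or cko replicate 2 (0.0652). The γδ T call was lost without ctr replicate 1 (0.0734), ctr replicate 3 (0.0742) or cko replicate 1 (0.0926).

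**Figure D2:**
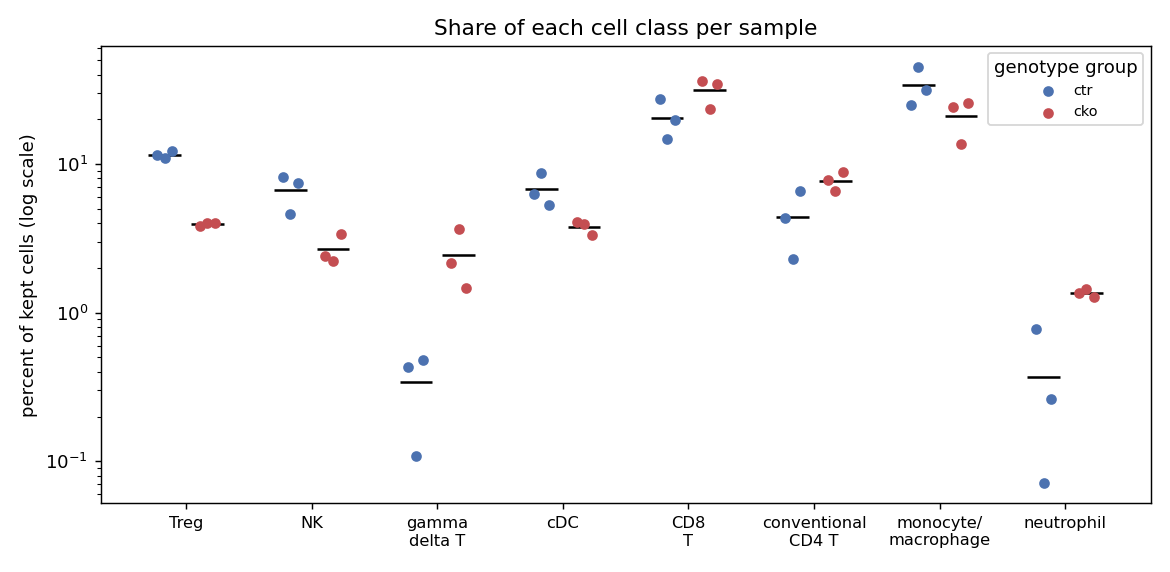
Percent of kept cells in each of 8 classes (log axis), with 1 point per sample for ctr and cko and a line at each group mean. Treg cells average 11.5% in ctr and 3.94% in cko, and γδ T cells 0.339% and 2.43%.

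Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) gave a view of the Treg compartment that does not rest on the border between the Treg and conventional CD4 T clusters. After thinning to equal depth, a Foxp3 UMI was found in 12.9% ± 2.00 of Treg plus conventional CD4 T cells in ctr and 6.79% ± 0.482 in cko (exact p = 0.1). Without thinning the shares were 22% ± 4.86 and 11.1% ± 0.190. Within the Treg class, which was drawn on Foxp3 among other markers, the thinned shares were 15.7% ± 1.66 and 18.9% ± 3.09 (exact p = 0.2). Conventional CD4 T cells had 3.24% ± 1.46 in ctr and 0.717% ± 0.174 in cko (exact p = 0.1). CD8 T cells, which should lack Foxp3, gave a background of 0.120% ± 0.0246 and 0.177% ± 0.0439. Median depth per sample was 4682 to 5797 UMIs in CD4 and 6782 to 8664 UMIs in CD8 T cells, and thinning left out 310 ctr and 209 cko CD4 T cells.

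The second comparison asks which genes differ within the Treg cells that remain after the deletion, from sums of 1221333 to 4771443 counts per sample. The chemokine receptor Ccr2 went from 76.1 ± 29.4 to 417 ± 62.6 CPM (log2 2.46, SE 0.31, adjusted p = 0.0110). The lipid-sensing receptor Gpr18 went from 3.62 ± 1.13 to 48.2 ± 7.95 CPM (log2 3.75, SE 0.24, adjusted p = 7.21e-07) and the killing protease Gzmb from 284 ± 121 to 1053 ± 55.9 CPM (log2 1.89, SE 0.35, adjusted p = 0.0444). The interferon-induced gene Ifitm1 rose from 3.46 ± 3.62 to 59.6 ± 24.4 CPM (log2 4.18, SE 0.72, adjusted p = 0.0385). Sfn (log2 2.36), Clec2i (2.01), Perp (1.86) and Ahi1 (1.73) followed, with adjusted p from 4.16e-06 to 0.00196. Among lower genes were the secreted phosphoprotein Spp1 (245 ± 31.0 to 37.8 ± 21.1 CPM, log2 -2.66, SE 0.36, adjusted p = 0.0153) and the ectoenzyme Cd38 (35.2 ± 4.20 to 10.0 ± 4.05 CPM, log2 -1.82, SE 0.24, adjusted p = 0.000328). The tetraspanin Cd81 (463 ± 96.6 to 143 ± 8.32 CPM, log2 -1.69, SE 0.14, adjusted p = 1.49e-05) and the mitochondrial ribosomal protein gene Mrpl23 (117 ± 11.9 to 35.4 ± 3.47 CPM, log2 -1.72, SE 0.14, adjusted p = 4.57e-06) were lower too. Gda (-2.84), Bmyc (-2.41), Gimap8 (-1.68) and Tox2 (-1.67) were also lower. In every gene called higher or lower by name in any class, all 3 cko samples lay on one side of all 3 ctr samples, as the rule for naming the genes of largest change required. Chance gives 10% of unchanged genes that placement, and 16.4% (conventional CD4 T) to 42.6% (monocytes and macrophages) of all tested genes had it.

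The list of Treg identity genes was not called by camera in these cells, which tests for a common shift, but its members moved both ways. Of its 24 tested members 2 were higher, 8 lower and 14 not called (6 and 9 when adjusted over the list alone), and camera gave an adjusted p of 0.268. Members were thus called more often than tested genes at large, of which 415 were higher and 335 lower of 9645. Several define the class. Foxp3 stood at 76.6 ± 8.44 and 88.6 ± 16 CPM (log2 0.21, SE 0.14, adjusted p = 0.424). Il2ra, Ctla4 and Ikzf2 did not pass either (log2 0.45, 0.29 and 0.13, adjusted p = 0.122, 0.616 and 0.521). The co-stimulatory receptor Tnfrsf18, likewise a class marker, fell (log2 -0.41, SE 0.12, adjusted p = 0.0441). The suppressive cytokine Il10, the effector cytokine Ifng, its regulator Tbx21, the memory factor Tcf7 and the alarmin receptor Il1rl1 gave log2 changes of -0.48, -0.61, -0.11, 1.06 and 0.26, with adjusted p = 0.65, 0.265, 0.831, 0.282 and 0.538. Of 24 interferon gamma response genes 3 were higher and none lower (5 and none adjusted over the list alone): Socs1, a brake on cytokine signalling (223 ± 18.1 to 544 ± 41.5 CPM, log2 1.29, SE 0.10), Cd274, which encodes PD-L1 (log2 0.79), and the GTPase Gbp3 (log2 1.12). The list was called higher by camera (adjusted p = 0.00144, and 0.805 with an estimated correlation). Proliferation genes were called lower (17 tested, none higher, 3 lower, 1 and 4 adjusted over the list alone, adjusted p = 0.0232, and 0.805 with an estimated correlation), with Mcm5 (log2 -0.88), Tyms (-0.73) and Mcm3 (-0.57) past the threshold. Of 15 exhaustion genes none were higher and 4 lower (adjusted p = 0.0802, 0.736 with an estimated correlation, and 0.0069 by fry, which tests against no change and not against other genes). The Th1 and effector list (2 higher and 1 lower of 20, with camera up but a median of -0.03 and a mean of -0.14) and the cytotoxicity list (2 higher and 3 lower of 13) each had an adjusted p of 0.913.

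Lists of other cells and of handling were called in the same sums. Transcripts of macrophages were called lower (12 tested, none higher, 1 lower, none and 6 adjusted over the list alone, adjusted p = 0.000479, and 0.736 with an estimated correlation), as was the suppressive macrophage list (11 tested, 2 lower, with Spp1 and Fabp5 past the threshold, adjusted p = 0.0211, and 0.805 with an estimated correlation). Dissociation stress genes were lower too (19 tested, none higher, 3 lower, none and 5 adjusted over the list alone, adjusted p = 0.00144, and 0.805 with an estimated correlation), led by the immediate early genes Egr1 (log2 -0.56) and Dusp1 (-0.78) and the chaperone Hsp90aa1 (-0.75). Cluster 0 of the T and NK cells held 90.3% of ctr but 22.4% of cko Treg cells, and cluster 11 held 1.73% and 74.6%. In all, 750 of 9645 genes passed, 415 higher and 335 lower, and 443 (256 and 187) with cko replicates 1 and 3 added together, of which 426 were among the 750. With that addition Ctcf, Tnfrsf18, Gzmb, Bmyc, Tox2, Mcm3, Fabp5, Dusp1 and Hsp90aa1 no longer passed. The count was 380 without cko replicate 1 and 341 without cko replicate 3.

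The third comparison asks whether conventional CD4 T cells, which are not the target of the deletion, differ too. The residency receptor Cxcr6 rose from 369 ± 27.3 to 855 ± 90.8 CPM (log2 1.22, SE 0.12, adjusted p = 0.00112; n = 3 per group), and the killer lectin receptors Klrc1 (log2 1.43, adjusted p = 0.0259) and Klrk1 (1.02, 0.00698) rose with it. Pxdc1 (log2 1.89), the protease inhibitor Serpinb1a (1.54), Nabp1 (1.48) and Ern1 (1.33) were also higher. Foxp3 fell from 14.9 ± 7.14 to 3.19 ± 0.629 CPM (log2 -2.30, SE 0.37, adjusted p = 0.0136). It is a marker of the Treg class, which made up 73.3% of Treg plus conventional CD4 T cells in ctr and 34.0% in cko. Whether Treg cells or their free RNA in this class account for the fall was not tested. The heat shock genes Hspa1a (log2 -1.74), Hspa1b (-1.64) and Dnajb1 (-1.46), the transcription factor Irf8 (-1.44) and the macrophage lysozyme gene Lyz2 (-0.96) were lower. Ifng (298 ± 173 and 229 ± 42.2 CPM, adjusted p = 0.891), Tbx21 (log2 0.51, 0.588), Gzmb (0.58, 0.193), Pdcd1 (0.48, 0.586), Tcf7 (-0.04, 0.989), Il2 (-1.05, 0.704) and the class marker Cd40lg (0.24, 0.491) did not pass.

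Of 16 cytotoxicity genes in conventional CD4 T cells 2 were higher and none lower (7 and 1 adjusted over the list alone), and the list was called higher (adjusted p = 0.0181). The lists called lower were dissociation stress (19 tested, 5 lower, adjusted p = 4.96e-06), type I interferon response (22 tested, none past the threshold, 0.00254), macrophage transcripts (12 tested, 1 lower, 0.00298), interferon gamma response (24 tested, 1 lower, 0.0183), MHC class II (8 tested, none, 0.0244) and suppressive macrophage (11 tested, none, 0.0244). With an estimated correlation the adjusted p was 0.672 for each of these 7 lists. The Th1 and effector list was not called (21 tested, 2 higher, adjusted p = 0.141; median 0.24, mean -0.14). Cluster 4 of the T and NK cells held 28.5% of ctr and 64.7% of cko cells of this class, cluster 7 held 46.2% and 33.4%, and cluster 21, led by Ccr6 and Il17re, held 25.3% and 1.99%. Of 9249 genes 61 passed, 42 higher and 19 lower, and 10 with cko replicates 1 and 3 added together (9 shared; 8 higher and 2 lower). Foxp3 then stood at an adjusted p of 0.0503, and Klrc1, Ern1, Hspa1a, Dnajb1, Irf8 and Lyz2 no longer passed either. The count was 32, 103 and 18 without ctr replicates 1 to 3 and 11, 231 and 9 without cko replicates 1 to 3.

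All CD4 T cells taken as 1 sum mixed Treg, conventional and unresolved CD4 T cells in different proportions. In cko replicate 2, unresolved cells were 609 of 1226, and of its 10798063 UMIs Treg cells held 1221333 and conventional CD4 T cells 2364992, so that sum is mostly neither class. Foxp3 (log2 -1.07, SE 0.17, adjusted p = 0.033) and Ikzf2 (-0.92, 0.033) fell, as did the TGF-beta-presenting receptor gene Lrrc32 (-1.99, 0.033), Klrg1 (-2.29, 0.0208), Cd81 (-2.02, 0.0126) and Spp1 (-3.03, 0.0185). Ifitm1 rose from 12.2 ± 1.02 to 168 ± 55.5 CPM (log2 3.79, SE 0.26, adjusted p = 0.00488), Cd7 by 2.57 (0.0416) and Klrk1 by 1.78 (0.0114). Of 24 Treg identity genes 1 was higher and 7 lower (1 and 15 adjusted over the list alone, adjusted p = 8.09e-10, and 0.377 with an estimated correlation). The stem-like and memory list was called higher (16 tested, 1 higher, adjusted p = 0.000564, and 0.452 with an estimated correlation). These sums include a cluster led by Igfbp4 and Tcf7 with 424 of its 445 cells in cko replicate 2. Called higher as well was cytotoxicity (17 tested, 3 higher and 1 lower, 0.0144, and 0.377). Exhaustion (15 tested, 3 lower, adjusted p = 0.000608, and 0.452 with an estimated correlation) was called lower. So were macrophage transcripts (14 tested, 1 lower, none and 9 adjusted over the list alone, 1.11e-07, and 0.377 with an estimated correlation) and dissociation stress (19 tested, none past the threshold, none and 8 adjusted over the list alone, 8.89e-06, and 0.452), lists of another cell type and of handling. Type I interferon response (24 tested, none, 2.44e-06, and 0.563 with an estimated correlation), suppressive macrophage (13 tested, 1 lower, 2.04e-05, and 0.377), MHC class II (11 tested, none, 0.000115, and 0.377), hypoxia and glycolysis (21 tested, none, 0.000533, and 0.595), MHC class I (18 tested, none, 0.00165, and 0.591) and interferon gamma response (26 tested, 1 lower, 0.0273, and 0.705) were called lower too. Cohesin and CTCF genes (13 tested, none, 0.00743, and 0.452 with an estimated correlation) and proliferation (22 tested, none, 0.0273, and 0.742) were called higher, and the proliferation list reversed without cko replicate 2. Of 11045 genes 128 passed, 41 higher and 87 lower, and 6 with cko replicates 1 and 3 added together. Of the genes named in this paragraph, all but Ifitm1 then no longer passed. The count was 18, 7 and 16 without ctr replicates 1 to 3 and 6, 539 and 18 without cko replicates 1 to 3. With all 6 libraries kept, it was 25 with a replicate block, 358 by DESeq2 and 227 at the higher resolution.

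**Figure D3:**
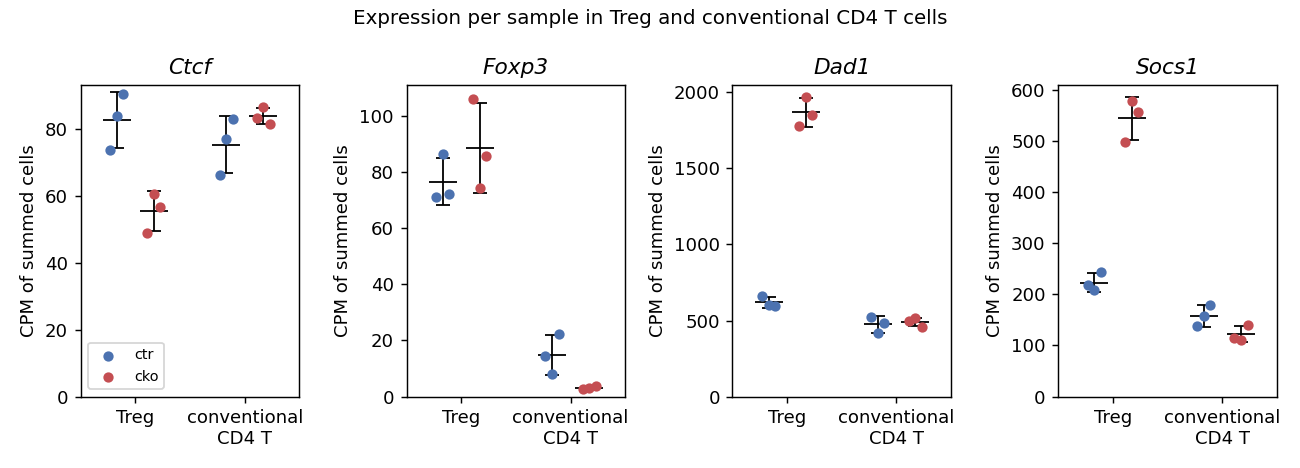
CPM of Ctcf, Foxp3, Dad1 and Socs1 in sums of Treg and of conventional CD4 T cells, with 1 point per sample and bars for the mean ± SD (n = 3 per group, axes from 0). In Treg cells Ctcf falls from 82.8 to 55.5 CPM and Dad1 rises from 620 to 1867 CPM, while Dad1 in conventional CD4 T cells stands at 474 and 490 CPM.

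Whether the genotype effect differed between the class with the deletion and the CD4 class without it was tested directly. The interaction passed for 343 of 9808 genes, 123 more positive and 220 more negative in Treg cells, and for 233 with cko replicates 1 and 3 added together. Ctcf itself differed by -0.73 on the log2 scale (adjusted p = 0.00955). Dad1, an oligosaccharyltransferase subunit gene (ENSMUSG00000022174, chromosome 14, 54235479 to 54254104, minus strand), showed the smallest p. In Treg cells it rose from 620 ± 35.5 to 1867 ± 95.7 CPM (log2 1.59, SE 0.09, adjusted p = 6.74e-07). In conventional CD4 T cells it was 474 and 490 CPM. The difference was 1.54 for Dad1 (adjusted p = 5.72e-08), 1.65 for Socs1 (9.09e-07), 2.56 for Foxp3 (0.00140) and 0.62 for Il2ra (0.0346). That of Foxp3 came from conventional CD4 T cells (log2 -2.24, against 0.18 in Treg cells, both without a filter on low counts). Foxp3 and Il2ra are also markers that the Treg class was drawn on. Of the 343 genes, 213 were also called in the Treg comparison. With cko replicates 1 and 3 added together the Il2ra call was lost (0.54, adjusted p = 0.150). Gzmb (1.44, 0.219), Pdcd1 (-0.97, 0.228) and Tbx21 (adjusted p = 0.0521) did not pass. The count was 202 without ctr replicate 3, 196 without cko replicate 1 and 178 without cko replicate 3.

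CD8 T cells, the class that kills infected and tumour cells, were compared to see whether they differ in mice with the deletion in Treg cells. The largest clonotype held 951 of 1892 CD8 T cells with both TCR chains in cko replicate 1 and 804 of 1831 in cko replicate 3. It held 87 of 1207 in cko replicate 2, and 202 of 1411, 247 of 719 and 172 of 1146 in ctr replicates 1 to 3. Whether the state of single large clonotypes accounts for part of the gene differences in this class was not tested. The granzyme gene Gzmb, on which the class was partly drawn, rose from 1007 ± 138 to 2153 ± 85.1 CPM (log2 1.10, SE 0.10, adjusted p = 0.00162; n = 3 per group). Havcr2, the checkpoint receptor TIM-3, rose from 90.4 ± 9.47 to 162 ± 2.79 CPM (log2 0.84, SE 0.09, adjusted p = 0.00284), while Pdcd1 (PD-1) rose by 0.49 (0.0326) and Il7r, the interleukin-7 receptor, by 0.69 (0.0166). Tox, a transcription factor of exhausted T cells, fell from 163 ± 30 to 74.8 ± 7.33 CPM (log2 -1.13, SE 0.13, adjusted p = 0.00485). The residency factor Zfp683 fell from 38.8 ± 7.04 to 8.45 ± 0.402 CPM (log2 -2.19, SE 0.14, adjusted p = 0.000405). Lmna (log2 2.63), the integrins Itgb3 (1.64) and Itgb7 (1.38), Serpine2 (1.60), Rora (1.55), Anxa1 (1.5), Emb (1.4) and Ccr2 (1.35) were higher. Chn2 (-1.88), Myc (-1.60), Itih5 (-1.43), the survival gene Bcl2 (-1.31) and Fos (-1.27) were lower. Ifng (578 ± 130 and 582 ± 66.8 CPM, adjusted p = 0.976), Tcf7 (log2 -0.26, 0.532), Mki67 (0.00, 0.992) and the marker Prf1 (0.37, 0.0643) did not pass.

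Of 17 cytotoxicity genes in CD8 T cells 3 were higher, Fasl, Klrc1 and Gzmb, and 1 lower, Cst7 (6 and 3 adjusted over the list alone), and the list was called higher (adjusted p = 0.00988, and 0.726 with an estimated correlation). Interferon gamma response genes were called higher with Gbp2, Gbp3 and Cd274 (26 tested, 3 higher, none lower, 5 and 1 adjusted over the list alone, adjusted p = 0.00988, and 0.779 with an estimated correlation). The Th2, Th17 and Tfh list was called higher with Rora and Bcl6 past the threshold (6 tested, adjusted p = 0.0236, and 0.726 with an estimated correlation). MHC class II (10 tested, 2 lower, none and 8 adjusted over the list alone, 6.99e-05), dissociation stress (19 tested, 2 lower, 8.99e-05), macrophage transcripts (15 tested, none, 0.00988) and mitochondrial transcripts (13 tested, none, 0.0176) were called lower, with adjusted p of 0.726, 0.767, 0.767 and 0.779 with an estimated correlation. Exhaustion genes moved both ways, 3 higher and 4 lower of 16 (adjusted p = 0.905; camera pointed down, the mean was -0.09 and the median 0.01). Cluster 2 of the T and NK cells held 3.64% of ctr and 26.0% of cko CD8 T cells, cluster 1 held 32.6% and 11.2%, and cluster 9 held 17.0% and 1.62%. In all, 620 of 11583 genes passed, 308 higher and 312 lower, and 129 (76 and 53) with cko replicates 1 and 3 added together, where Pdcd1, Il7r, Serpine2, Rora, Anxa1, Itgb7, Fos, Cst7, Fasl, Klrc1, Gbp2, Gbp3 and Cd274 no longer passed. The count was 387 without ctr replicate 2, 218 without ctr replicate 3, 129 without cko replicate 1 and 87 without cko replicate 3.

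NK cells were compared to see whether the cells that make up this smaller share of the infiltrate differ. Il18r1 rose from 52.9 ± 2.84 to 98.1 ± 13.9 CPM (log2 0.91, SE 0.12, adjusted p = 0.00219; n = 3 per group), the interleukin-12 receptor gene Il12rb2 by 0.74 (0.0227) and its signal transducer Stat4 by 0.64 (0.0055). They are the 3 of 19 members called in the Th1 and effector list, which was called higher (adjusted p = 0.0125, and 0.81 with an estimated correlation). The stem cell factor receptor Kit (log2 1.75, adjusted p = 0.0401), Krt83 (2.46, 7.17e-05), Camk4 (1.65, 0.00434) and Gpr183 (1.08, 0.0031) were higher, and Itih5 (-1.18), Osbpl1a (-1.09), Tmsb15a (-1.03) and Id3 (-0.97) lower. Ifng (log2 0.05), Gzmb (-0.20) and Prf1 (-0.19) did not pass (adjusted p = 0.945, 0.74 and 0.401). Proliferation (22 tested, none past the threshold, adjusted p = 0.0236), hypoxia and glycolysis (20 tested, none, 0.0243), dissociation stress (19 tested, 1 lower, 0.0243) and macrophage transcripts (12 tested, none, 0.0243) were called lower, with adjusted p of 0.809 to 0.81 with an estimated correlation. Cluster 5 of the T and NK cells held 63.5% of ctr and 49.5% of cko NK cells and cluster 13 held 25.5% and 46.0%. Of 9398 genes 93 passed, 56 higher and 37 lower, and 39 with cko replicates 1 and 3 added together, where Kit, Il12rb2 and Id3 no longer passed. Naming the clusters of low UMI count by their markers, an alternative chosen after seeing the data, gave 1234 called genes (612 higher and 622 lower). The count was 154 without ctr replicate 1, 41 without ctr replicate 3, 34 without cko replicate 1, 46 without cko replicate 2 and 19 without cko replicate 3. It was 452 (216 higher and 236 lower) without a filter on low counts and 165 with a replicate block. Without ctr replicate 1 no list was called.

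Monocytes and macrophages differed in more genes than any other class tested. The complement genes C1qa (3201 ± 430 to 804 ± 98.6 CPM, log2 -1.99, SE 0.12, adjusted p = 6.67e-05), C1qb and C1qc (log2 -1.64 and -1.72) fell. The lipid carrier gene Apoe fell as well (10384 ± 1681 to 2220 ± 364 CPM, log2 -2.23, SE 0.15, adjusted p = 0.000112). Arg1, the arginine-degrading enzyme, rose from 902 ± 203 to 1881 ± 148 CPM (log2 1.06, SE 0.16, adjusted p = 0.00252). The class was drawn on these 5 genes. Il1b, the inflammatory cytokine, rose from 4846 ± 149 to 8712 ± 779 CPM (log2 0.85, SE 0.08, adjusted p = 0.000255). Cd274 rose from 178 ± 52.2 to 351 ± 19.3 CPM (log2 0.98, SE 0.18, adjusted p = 0.00805) and the arginine transporter gene Slc7a2 from 17.2 ± 4.90 to 141 ± 18.0 CPM (log2 3.05, SE 0.20, adjusted p = 0.000112). Ramp3 (log2 3.74), Slc4a11 (3.28), Dcstamp (2.70), Srxn1 (2.67), the growth factor Areg (2.55), Ccl24 (2.44) and the matrix protease Mmp19 (2.43) were higher. Olfml3 (-2.68), Cd81 (-2.50), Cd72 (-2.39), the chemokine Ccl8 (-2.34), Tmem119 (-2.33) and Tmem176b (-2.09) were lower, as were H2-Aa (-0.32, adjusted p = 0.0402) and the marker Spp1 (-0.71, 0.000564). Cxcl9 (0.27, 0.151), Cxcl10 (-0.09, 0.575), the marker Mrc1 (-0.53, 0.354) and Nos2, the nitric oxide synthase (2.64, SE 0.75, 0.0649), did not pass. Within the cluster that held most cko cells, Arg1, Il1b and Cd274 did not pass either (log2 0.37, 0.22 and 0.50). There C1qa (-0.99), Apoe (-1.90) and Slc7a2 (2.20) still did.

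Proliferation genes were called lower in these cells (22 tested, none higher, 14 lower, none and 16 adjusted over the list alone, adjusted p = 2.24e-06, and 0.493 with an estimated correlation), with Ccnb2 (log2 -2.76) and Mcm3 (-1.03) as examples. Hypoxia and glycolysis genes were called higher (22 tested, 13 higher, none lower, 15 and none adjusted over the list alone, 2.24e-06, and 0.493 with an estimated correlation), among them the vessel growth factor Vegfa (log2 1.30) and the hexokinase Hk2 (0.90). So were interferon gamma response genes such as Socs1 (0.82), with 11 of 27 higher and none lower (14 and none adjusted over the list alone, 8.14e-05, and 0.493 with an estimated correlation). Inflammatory macrophage genes were called higher (20 tested, 7 higher and 2 lower, 8 and 2 adjusted over the list alone, 0.00234) with Il6 (log2 2.06), Cd80 (1.35) and Il1rn (1.13), and MHC class II genes lower (12 tested, 6 lower, none and 9 adjusted over the list alone, 0.00245) with H2-Eb1 (-0.49) and Cd74 (-0.44). With an estimated correlation the adjusted p was 0.493 for the inflammatory and the MHC class II list. The suppressive macrophage list moved both ways, 6 higher and 8 lower of 18 (adjusted p = 0.281).

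Lists of handling and of other cells were called in the macrophage sums as well. Macrophage transcripts themselves (15 tested, 1 higher and 9 lower, adjusted p = 9.13e-05) and dissociation stress genes (19 tested, 2 higher and 9 lower, 0.00486) were called lower, and T cell transcripts (13 tested, 1 higher, Trbc1, 0.000523) and cytotoxicity genes (16 tested, 2 higher, 0.0297) higher, with adjusted p of 0.344, 0.344, 0.555 and 0.555 with an estimated correlation. Cluster 0, led by Arg1, Nos2 and Il1rn, held 36.0% of ctr and 77.5% of cko cells of this class. Cluster 3, led by Apoc2 and Apoe, held 39.1% and 9.93%, and cluster 12, led by Ccl8 and C1qa, 16.5% and 2.72%. In all, 2713 of 11341 genes passed, 1406 higher and 1307 lower, and 1621 (860 and 761) with cko replicates 1 and 3 added together, of which 1589 were among the 2713 and Ccl24 and Ccl8 were not. The count was 1555 without ctr replicate 3, 1343 without cko replicate 1 and 1646 without cko replicate 3.

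cDC were compared to see whether antigen-presenting cells differ as well. Ccr7, the lymph node homing receptor and a class marker, rose from 270 ± 80 to 775 ± 199 CPM (log2 1.52, SE 0.27, adjusted p = 0.0205; n = 3 per group), and the co-stimulatory genes Cd86 (log2 0.64, 0.0199) and Cd80 (1.11, 0.00939) rose too. The activin gene Inhba (log2 4.52, SE 0.67, adjusted p = 0.0157), Slc4a11 (3.25), Mmp19 (3.21), Areg (3.12), Thbs1 (3.08), Nrg1 (2.97) and the cystine transporter gene Slc7a11 (2.72, SE 0.21, 0.000541) were higher, and Siglece (-2.26), Pclaf (-2.13), Tk1 (-1.93), Stmn1 (-1.86) and Mcm7 (-1.71) lower. Proliferation genes were called lower (22 tested, none higher, 12 lower, none and 21 adjusted over the list alone, adjusted p = 4.45e-11). Interferon gamma response genes were called higher (27 tested, 11 higher, none lower, 13 and none adjusted over the list alone, 2.37e-07) with Cd274 (log2 1.17) and Gbp2 (0.98). Inflammatory genes (18 tested, 8 higher, 0.00125; Cxcl2 1.04, Il1b 0.94) and hypoxia and glycolysis genes (22 tested, 6 higher, 3.75e-05; Vegfa 2.03) were called higher, and the adjusted p was 0.55 with an estimated correlation for these 4 lists. Il12b (log2 0.24), Cd40 (0.38), H2-Aa (0.09) and Cxcl9 (0.66) did not pass (adjusted p = 0.693, 0.209, 0.668 and 0.19).

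T cell transcripts were called higher in cDC sums (11 tested, 1 higher, 10 and none adjusted over the list alone, adjusted p = 0.000229, and 0.55 with an estimated correlation) and dissociation stress genes lower (19 tested, 7 lower, 0.00125, and 0.55). Cluster 7 held 91.4% of ctr and 91.5% of cko cDC. Many cDC calls were also calls in monocytes and macrophages, among genes tested in both. These were 335 of 476 higher and 183 of 337 lower calls, where independent lists would share 62.6 and 39.9. Whether free RNA or cells of that class among the cDC add to this was not tested. In all, 857 of 10001 genes passed, 480 higher and 377 lower, and 231 (132 and 99) with cko replicates 1 and 3 added together, where Ccr7, Cd86, Stmn1, Cxcl2 and Il1b no longer passed. A mitochondrial maximum of 5 percent, with all 6 libraries kept, gave 250 called genes. The count was 568, 371 and 521 without ctr replicates 1 to 3 and 149, 1461 and 158 without cko replicates 1 to 3.

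The TCR data ask how clonal each T cell class is and whether conventional CD4 T cells carry receptors of Treg cells, the trace that Treg cells which lost their identity would leave. Expanded clonotypes held 30.7% ± 4.83 of Treg cells in ctr and 26.4% ± 10.6 in cko (exact p = 0.7; n = 3 per group). They held 7.89% ± 5.04 and 20.4% ± 14.3 of conventional CD4 T cells (exact p = 0.3) and 79.8% ± 3.29 and 83.9% ± 1.72 of CD8 T cells (exact p = 0.1, the smallest possible), after drawing 148, 101 and 719 cells per sample. The inverse Simpson index, an effective number of clonotypes, was 58.9 ± 11.6 and 67.9 ± 19.2 in Treg (exact p = 0.6), 78.7 ± 9.55 and 57.7 ± 22.3 in conventional CD4 T (exact p = 0.3) and 17.2 ± 8.70 and 13.5 ± 15.8 in CD8 T cells (exact p = 0.8). One CD8 T clonotype took 951 of 1892 cells (50.3%, 95% interval 48.0% to 52.5%) in cko replicate 1 and 804 of 1831 (43.9%, 41.7% to 46.2%) in cko replicate 3. The top clonotype of cko replicate 2 held 87 of 1207 (7.21%, 5.88% to 8.81%). In ctr the top clonotypes held 202 of 1411, 247 of 719 and 172 of 1146 cells. Clonotypes per 100 cells were 67.1 ± 4.42 and 70.8 ± 9.02 in Treg, 88.8 ± 4.81 and 77.6 ± 11.7 in conventional CD4 T and 23 ± 3.70 and 18.5 ± 2.53 in CD8 T cells (exact p = 0.6, 0.3 and 0.2).

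Conventional CD4 T cells with a clonotype also seen in Treg cells of the same sample made up 2.88% ± 1.21 in ctr and 4.48% ± 5.30 in cko (exact p = 1; n = 3 per group). Over all cells, without drawing equal numbers, the cko samples had 7 of 419 (1.67%, 95% interval 0.812% to 3.41%), 4 of 286 (1.4%, 0.545% to 3.54%) and 59 of 474 (12.4%, 9.77% to 15.7%) for replicates 1 to 3. The ctr samples had 19 of 212 (8.96%, 5.81% to 13.6%), 5 of 101 (4.95%, 2.13% to 11.1%) and 10 of 348 (2.87%, 1.57% to 5.21%), a mean of 5.6% against 5.17% in cko. With equal numbers drawn, leaving out cko replicate 3 turned the difference to -1.45 percentage points. Intervals are Wilson intervals and cover counting error only. CD8 T cells sharing a Treg clonotype, given as background, made up 0.0264% ± 0.0457 in ctr and 1.94% ± 3.32 in cko, with 5.77% in cko replicate 2. Clonotypes of Treg cells from another sample were found in none of the ctr and 0.479% ± 0.660 of the cko conventional CD4 T cells. The cko value came from replicates 1 and 3 alone (1.23% and 0.204%), the pair that shares clonotypes. With that pair added together it was 0 in every sample. No difference in sharing was thus detectable beyond the spread between samples, and with cko replicates 1 and 3 added together the cko mean was 3.26% (exact p = 1; smallest possible 0.2).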

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

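Of the tests in this part, those on shared clonotypes and the counts over other splits of the samples were chosen only after the result was seen.

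The genotype effect differed between Treg and conventional CD4 T cells for 343 genes by a test of the difference itself. Among the named ones, the log2 change in Treg minus that in conventional CD4 T cells was 1.54 for Dad1, 1.65 for Socs1, 2.30 for Grasp, 1.10 for Tomm20, 2.56 for Foxp3 and 0.62 for Il2ra, whose call was lost with cko replicates 1 and 3 added together (adjusted p = 0.150). It was -1.49 for Mdp1, -1.49 for Mrpl23, -1.44 for Ramp3, -0.70 for Rps15a and -0.73 for Ctcf. Without a filter on low counts, Ramp3 changed by 1.30 in conventional CD4 T cells and by -0.17 in Treg cells. Foxp3, a marker of the Treg class as is Il2ra, changed by -2.24 and 0.18 in the same order.

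In Treg cells 750 genes differed between the groups. Equal numbers of Treg cells drawn from every sample still gave 606 called genes (521 shared with the 750), so the smaller number of cko cells is not the whole cause. Among Treg cells with a Foxp3 UMI the median ratio of the log2 change to that of the class was 1.02, which argues against cells of other types in the class. Of the called genes 93.6% moved further in Treg cells than in the other kept cells or the opposite way. These genes were picked for their change in Treg cells, which by itself favours that outcome. Free RNA is therefore argued against only for the 243 of 750 genes that moved the opposite way. It stays open for other genes, such as Spp1. Called genes lay next to called genes 1.32 times as often as random genes did, at percentile 99.55 of 10000 random draws. The ratio was 1.14 each in CD8 T cells and macrophages and 1.53 in cDC, classes that the deletion does not target. The SDs (0.117 in Treg and 0.103 in cDC) are those of the random draws, so they do not show that the ratios differ. The comparison therefore cannot decide whether lost boundaries between neighbours are part of the cause. Treg calls were also shared with classes that the deletion does not target. With CD8 T cells 70 higher and 48 lower calls were shared, against 11.7 and 8.34 for independent lists. With cDC these were 76 and 25, against 15.7 and 9.26. Of the 750 genes, 213 also passed the interaction. A direct effect of the deletion on the cells that remain may explain part of the differences, while selection of Treg states that survive it and a response to the changed tumour stay open and untested.

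In monocytes and macrophages, which the deletion does not target, 2713 genes differed. The mix of clusters differed as well, and within the cluster that held most cko cells the median ratio of the log2 change to that of the class was 0.722, with 926 of the called genes still called, which argues against the mix as the whole cause. Arg1 (log2 0.37), Il1b (0.22) and Cd274 (0.50) did not pass within that cluster, so their differences may come in part from the mix. RNA of T cells in the cko droplets is argued against as the whole cause, since 47.2% of the genes called higher had a higher CPM in T and NK cells of ctr samples, against 51.4% of those called lower and 61.3% of those tested. A response of these cells to the loss of Treg function stays open and was not tested.

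The 191 paired clonotypes shared by cko replicates 1 and 3 stand far above the other pairs of samples. Barcodes carried between the libraries are argued against, since 0.0459% of cells of shared clonotypes in replicate 1 had the barcode of a cell of the same clonotype in replicate 3. Rearrangements common to many mice are argued against by the 3 clonotypes at most that any other pair shared. Sizes of the shared clonotypes went together (Pearson r = 0.861 across clonotypes, which are not independent replicates), so cells of 1 animal in both libraries are a candidate explanation. In that case the cko group would hold 2 animals, and the alternatives that add these libraries together are the ones to read.

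The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. For called genes the real split gave 128 in all CD4 T cells (1 split as large, the real one; highest other 0), 750 in Treg (1; highest other 1), 61 in conventional CD4 T (1; 5), 620 in CD8 T (1; 0), 93 in NK (1; 1), 2713 in monocytes and macrophages (1; 0), 857 in cDC (1; 0) and 343 in the interaction (1; 3). For called lists it gave 14 in all CD4 T cells (2 splits as large; highest other 14), 5 in Treg (6; 7), 7 in conventional CD4 T (2; 7), 7 in CD8 T (6; 9), 5 in NK (7; 8), 12 in monocytes and macrophages (1; 11) and 9 in cDC (2; 10). In every class but monocytes and macrophages another split thus called as many lists or more. In those classes the number of called lists does not set the genotype apart from other splits.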

How the results depend on the processing

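The joining of cko replicates 1 and 3, the naming of clusters of low UMI count, the use of named cells as the whole, the inclusion of unresolved CD4 T cells, and lists under other doublet, resolution and mitochondrial settings were tests chosen only after the result was seen. The cause was not tested for any change in this part, except that adding libraries together or leaving one out leaves fewer samples. Of 238 named calls, 146 (61.3%) kept their side of the threshold with cko replicates 1 and 3 added together, 128 without cko replicate 1, 134 without cko replicate 3, 201 without cko replicate 2 and 189, 180 and 168 without ctr replicates 1 to 3. DESeq2 kept 222 of 227, DESeq2 size factors 237 of 238, no filter on low counts 216 of 238 and the higher resolution 215 of 227. None reversed.

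With cko replicates 1 and 3 added together the called genes were 6 in all CD4 T cells, 443 in Treg, 10 in conventional CD4 T, 129 in CD8 T, 39 in NK, 1621 in monocytes and macrophages and 231 in cDC, and 3 lists in Treg. The NK share then changed by -1.38 (adjusted p = 0.0811), the γδ T share by 3.00 (0.0679) and the CD8 inverse Simpson index by 0.849. DESeq2 called 358 genes in all CD4 T and 115 in conventional CD4 T cells. Without a filter on low counts the calls were 1317 in Treg, 307 in conventional CD4 T, 452 in NK and 600 in the interaction. A mitochondrial maximum of 5 percent gave 250 genes in cDC and a cDC share of -1.18 (0.0309), and the lower resolution a cDC share of -1.06 (0.0302). The higher resolution gave 227 genes in all CD4 T and 92 in conventional CD4 T cells, and the proliferation list of all CD4 T cells reversed (adjusted p = 0.000159). Naming the clusters of low UMI count gave 147 genes in conventional CD4 T and 1234 in NK cells, and an NK share of -0.83 (0.0650). Doublets kept gave 4 lists in conventional CD4 T and 8 in NK cells.

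With an estimated correlation 0 lists were called in each of the 7 classes. By fry, which tests against no change and not against other genes, 1 list was called in Treg (exhaustion, adjusted p = 0.0069, which camera did not call), 8 in monocytes and macrophages and 0 in all CD4 T, conventional CD4 T, CD8 T, NK and cDC. Exact permutation of the shares gave -7.60 points for Treg, -4.04 for NK and 2.09 for γδ T (p = 0.1 each, the smallest possible). Over all cells without drawing, the Treg inverse Simpson index differed by -12.5 and the sharing of Treg clonotypes by -0.423 points, both reversed.

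With a replicate block the calls were 25 genes in all CD4 T and 165 in NK cells, and the shares changed by -1.55 for Treg (adjusted p = 0.0512), -1.31 for NK (0.0892) and 2.87 for γδ T (0.116). Over all kept cells the replicate numbers gave no sign of pairing, with correlations of -0.178, -0.259 and -0.0513 between samples of the same number. Within single classes these ranged from -0.117 (conventional CD4 T, number 3) to 0.248 (NK, number 1).

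Leaving out 1 library at a time, called genes ranged from 6 to 539 in all CD4 T cells, 341 to 727 in Treg, 9 to 231 in conventional CD4 T, 87 to 816 in CD8 T, 19 to 154 in NK, 1343 to 2846 in monocytes and macrophages, 149 to 1461 in cDC and 178 to 394 in the interaction. Called lists ranged from 10 to 14, 2 to 7, 4 to 9, 5 to 11, 0 to 7, 10 to 15 and 7 to 9 in the same order of classes. Log2 changes of shares ranged from -1.58 to -1.51 for Treg, -1.54 to -1.16 for NK, 2.40 to 3.17 for γδ T, -0.98 to -0.62 for cDC, 0.43 to 0.88 for CD8 T, 0.49 to 1.21 for conventional CD4 T, -0.86 to -0.41 for monocytes and macrophages, 1.39 to 3.00 for neutrophils, 0.28 to 0.66 for low UMI count, -0.55 to 2.29 for unresolved CD4 T, -0.25 to 4.82 for plasma and -0.0234 to 0.48 for unnamed cells. The last 3 reversed without cko replicate 2, as did the proliferation list of all CD4 T cells, whose adjusted p ranged from 4.10e-05 to 0.106 (0.106 without cko replicate 2).

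Differences in the expanded share ranged from -7.52 to 1.85 points in Treg, 7.07 to 20.7 in conventional CD4 T, 2.20 to 5.10 in CD8 T and -12.1 to 6.06 in all CD4 T cells. Those in the inverse Simpson index ranged from -1.53 to 17.2, -33.6 to -12.6, -12.8 to 1.17 and -32.0 to 97.6, and those in clonotypes per 100 cells from -1.39 to 7.10, -17.8 to -6.76, -6.08 to -2.47 and -4.43 to 11.6. The Treg and all CD4 T measures reversed without cko replicate 2, and the CD8 index without cko replicate 1 (1.17) or cko replicate 3 (0.596). The sharing of Treg clonotypes ranged from -1.45 to 3.17 points, the Foxp3-positive share from -6.67 to -4.92, the Treg share of CD4 T cells from -45.2 to -37.6 and the CD4 to CD8 ratio from -0.508 to -0.229. Depth and the spread between samples limit small changes. In simulated counts a log2 change of 1 was recovered for 63% of genes in Treg and 67% in conventional CD4 T cells, and for 85% in monocytes and macrophages.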

Other observations

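The tests of the neighbours of Dad1 and Ctla4 were chosen only after the result was seen, because CTCF helps to set which genes an enhancer can reach. Dad1 lies 11273 bp from Trac, the T cell receptor alpha constant gene, whose enhancer sits between them. In Treg cells Trac had a log2 change of 0.00 (adjusted p = 0.998), while Abhd4, 84 bp from Dad1 on its other side, rose by 0.94 (SE 0.14, adjusted p = 0.000986; n = 3 per group). In conventional CD4 T cells Abhd4 had a log2 change of 0.02 (adjusted p = 0.999). Next to Ctla4, which did not pass, the co-stimulatory genes Cd28 (113641 bp away, log2 0.86, adjusted p = 0.000129) and Icos (62095 bp away, log2 0.55, adjusted p = 0.00812) rose in Treg cells. Of the neighbours of the named interaction genes and the key genes, 1 each beside Foxp3, Ctcf, Mrpl23, Pdcd1 and Ifng also passed. The other neighbours, among them both of Socs1, Mdp1, Tomm20, Grasp, Ramp3 and Rps15a, did not. A neighbour here is the nearest tested gene on a side, which can be far away. Those that passed lay 1261070 bp from Pdcd1, 464299 bp from Mrpl23, 272049 bp from Ifng, 3352 bp from Ctcf and 0 bp from Foxp3. Of all genes tested in Treg cells, 750 of 9645 passed.

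Replicate 2 of cko stood apart in lymphocyte makeup. It held 215 of the 234 plasma cells and 424 of the 445 cells of a naive-like cluster of CD4 T cells. The expanded share of conventional CD4 T cells was 4.25% in cko replicate 2, within the range of ctr replicates 1 to 3 (12.3%, 8.91% and 2.42%). By this measure cko replicates 1 and 3, the pair that shares clonotypes, lay above ctr (31.4% and 25.7%).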
